A study of Mus musculus with 9 samples.

How the data were processed

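Poly(A)-primed transcripts were measured in 9 bulk libraries from sorted mouse brain endothelial cells, 3 libraries for each of 3 genotypes: WT, APP_PS1 and APP_PS1xRIPK1KD. Per the labels, the sorted population was positive for CD31 (Pecam1, an endothelial surface protein) and negative for CD45 (the leukocyte surface protein). The libraries followed Smart-seq2, in which first-strand cDNA is primed from the poly(A) tail and amplified by PCR, and the cDNA was fragmented and tagged by transposition before paired sequencing. The protocol keeps no strand information and carries no molecular identifiers, so PCR copies cannot be told from independent molecules, and the floors of 3 counts cover counting error only.

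The authors deposited a matrix of expected counts per gene symbol, the unit in which RSEM apportions reads among genes that share sequence. Their processing notes name Bowtie 0.12.2, RSEM without a version, edgeR 3.10.2 and the mouse build mm10 (GRCm38). The annotation is not given in the sources used here. Of the matrix values, 28.3% were not whole numbers, which is the form of RSEM output, and the column totals were unequal, which is the form of counts without normalization. The authors also deposited an edgeR table comparing APP_PS1 with WT, whose fold changes and abundances are in log2 units and whose test columns hold a p-value from a likelihood ratio test and its FDR. That table was used only to set the authors' values beside the ones computed here.

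Expected counts were rounded to whole numbers. Genes were kept by the edgeR function filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 13317 of the 23420 genes in the matrix. Library sizes were scaled by TMM factors. CPM values are counts scaled by the TMM-adjusted library size, and group values are means ± SD over 3 libraries. One edgeR quasi-likelihood model with robust dispersion and 1 coefficient per genotype was fitted to all 9 libraries, and 3 contrasts were tested 2-sided, each with Benjamini-Hochberg adjustment over the 13317 genes and an FDR threshold of 0.05. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are those of GENCODE M21 on GRCm38, matched by symbol.

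Before the data were examined, 29 gene lists with 612 members were fixed, 18 for endothelial and cellular functions and 11 for cell types that a brain homogenate or the sort gate could hold. Of the members, 605 matched the matrix by the same symbol, 5 by an older symbol and 2 not at all. Each list was tested against all other genes by limma camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 29 lists. The test was repeated with a correlation estimated for each list, which reached 0.76, and with fry, a rotation test of whether the members of a list move on balance in 1 direction. Summed CPM of each cell type list was compared between genotypes by an exact 2-sided permutation test, which cannot give a p under 0.1 with 3 libraries against 3.

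Genes were named by a rule fixed together with the lists. For each comparison it took up to 8 genes per direction past the FDR threshold, or otherwise the 5 with the smallest p, among genes of at least 5 CPM on average whose libraries did not overlap between the genotypes. It added up to 4 members per direction of each list past the threshold, or the 2 with the smallest p where camera called the list, and a fixed set that included Ripk1, Ripk3, Mlkl, Casp8, Tnfaip3, App, Nat1, Nat2, Cldn5, Pecam1 and Cdh5. Added after the values were seen were 4 lists, the targets of the glucocorticoid receptor and of heat shock factor and clock genes of the Dbp and Arntl phases. Some genes that the rule selects are counted but not reported here by name. Genes outside the rule are named as chosen after their values were seen.

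The fit was tested on simulated data with 200 changed genes per comparison, made from the dispersions of these libraries. Of genes changed 2-fold it recovered 41.8% in APP_PS1 against WT, 41.8% in APP_PS1xRIPK1KD against APP_PS1 and 29.9% in APP_PS1xRIPK1KD against WT. Of genes changed 4-fold it recovered 79.1%, 82.1% and 73.1%, and of genes changed 8-fold 89.4%, 87.9% and 92.4%. False calls numbered 9 of 155, 12 of 164 and 12 of 149. The list given a change was called in each comparison and 0 of the 28 unchanged lists were. The genes were simulated independently of each other, so this does not test camera on lists whose members are correlated. The changed genes were drawn only from genes above a low minimum CPM. With so many changed genes the adjustment was less strict than in the real comparisons, which called 3, 1 and 5 genes. The recovered shares therefore do not carry over to the real comparisons.

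Alternatives fixed together with the lists were DESeq2, the edgeR exact test, limma-voom, RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 3 libraries, a fit to the 6 libraries compared, the replicate number as a block, an FDR of 0.1, unrounded counts, and each library left out in turn. Alternatives chosen after seeing the data were a fit to replicates 1 and 2, replicate 3 as a term, removal of the ribosomal RNA precursor Rn45s, the edgeR likelihood ratio test on 9 and on 6 libraries, and the summed share of cytosolic ribosomal proteins with and without Rn45s in the total. No library was left out of the reported values.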

Results

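Transcript levels were measured in cerebral endothelial cells sorted from the brains of 6-month-old C57BL/6 mice of 3 genotypes. APP_PS1 mice are a transgenic model that deposits amyloid in the brain. APP_PS1xRIPK1KD mice carry in addition an alteration of Ripk1, a kinase of the tumour necrosis factor receptor pathway and of necroptosis, and are called the compound genotype from here on. The meaning of the abbreviation KD is not given in the sources used here. Each genotype had 3 libraries, each from 20000 cells, with total expected counts between 16263792 (APP_PS1 replicate 1) and 52413200 (APP_PS1 replicate 3) and a median of 46603518. At these depths a count of 0 allows up to 0.189 CPM in APP_PS1 replicate 1 and up to 0.0541 CPM in replicate 3 of the compound genotype, taking 3 counts as the floor. The design gives 3 comparisons: APP_PS1 against WT, the compound genotype against APP_PS1, and the compound genotype against WT.

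The libraries had an endothelial profile in all 3 genotypes. Cldn5, the main claudin of the tight junctions of the blood-brain barrier, stood at 6830 ± 957 CPM in WT, 6640 ± 1580 in APP_PS1 and 7650 ± 665 in the compound genotype (SD, n = 3 each). Pecam1, which encodes the CD31 used for sorting, stood at 1160 ± 81.1, 1130 ± 134 and 1210 ± 20.9 CPM, and the endothelial cadherin Cdh5 at 576 ± 21.7, 545 ± 51.1 and 599 ± 41.2 CPM. None of these 3 genes passed the FDR threshold in edgeR in any comparison. The ribosomal RNA precursor Rn45s took between 15.8% and 33.8% of the counts of a library, with means of 32.3% ± 2.32 in WT, 24.2% ± 7.31 in APP_PS1 and 23% ± 3.15 in the compound genotype. The exact permutation p for that share was 0.1, the smallest possible, for each of the other genotypes against WT, and 0.8 between them. Across all genes, the Pearson correlation of log2 CPM was 0.92 to 0.938 between libraries of 1 genotype and 0.908 to 0.934 between genotypes, where genes are not independent replicates.

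All 9 mice were labelled male. The non-coding RNA Xist, which silences an X chromosome in female cells, stood between 264 and 534 CPM in 6 libraries, replicates 1 and 2 of every genotype. In the same 6 libraries the sum of the 4 Y-linked transcripts Ddx3y, Eif2s3y, Uty and Kdm5d did not exceed 0.434 CPM. In the 3 libraries of replicate 3 that sum lay between 150 and 184 CPM and Xist did not exceed 4.78 CPM. The split was balanced across genotypes.

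**Figure D1:**
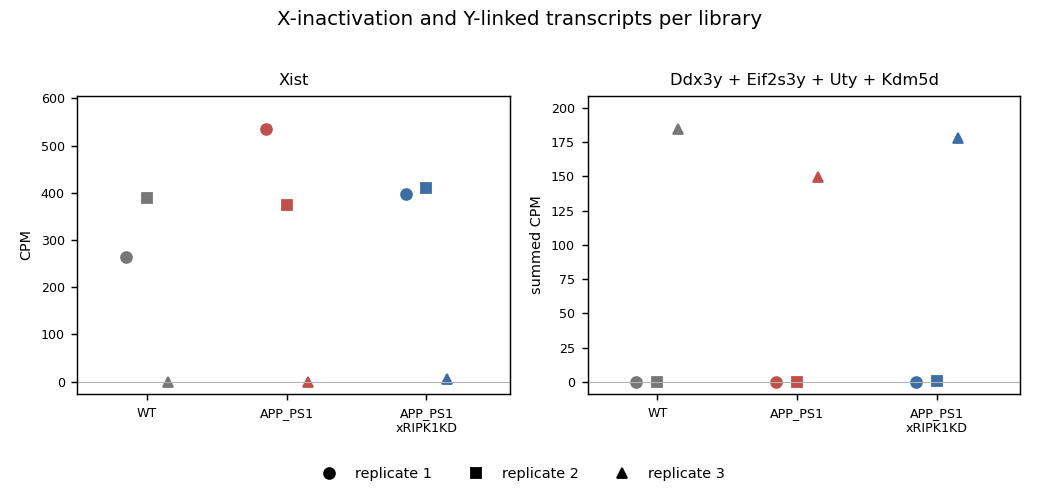
Xist (left, CPM) and the sum of Ddx3y, Eif2s3y, Uty and Kdm5d (right, summed CPM) in each of the 9 libraries, by genotype, with the symbol giving the replicate. Xist lies between 264 and 534 CPM in replicates 1 and 2 of every genotype, and the Y-linked sum lies between 150 and 184 CPM in replicate 3 of every genotype.

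Compared with WT, sorted cells of APP_PS1 mice carried more of 3 transcripts, of which Vtn and Atp13a5 are described here. Vtn, the extracellular matrix glycoprotein vitronectin, which brain pericytes express, was 7.9-fold higher at 53.5 ± 5.69 CPM against 6.79 ± 3.26 (log2 fold change 2.98 ± 0.365 SE, FDR 0.0135). Atp13a5, a P5-type ATPase expressed by brain pericytes, stood at 6.71 ± 2.29 CPM against 0.18 ± 0.104 (5.23 ± 0.651, FDR 0.0135). All 3 libraries of APP_PS1 lay above all 3 of WT for each of these genes. Vtn lies on chromosome 11 from 78499091 to 78502324 and Atp13a5 on chromosome 16 from 29231851 to 29378732, both protein-coding genes. No transcript was called lower. At an unadjusted p under 0.05 edgeR counted 465 genes higher and 353 lower, 818 in all against 666 expected by chance. DESeq2 called 35 higher and 10 lower.

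The 2 mural genes Vtn and Atp13a5 belong to a wider difference in transcripts of mural cells, the pericytes and smooth muscle cells that wrap brain vessels. Of the 16 members of that list, 15 had a fold change above 0, with a median log2 fold change of 2.62, and 11 were higher when adjusted over the list alone. Camera called the list higher (adjusted p = 1.17e-19, and adjusted p = 0.0858 with an estimated correlation), and fry called it too (adjusted p = 0.012). Summed over the list, mural transcripts stood at 44.6 ± 27.7 CPM in WT and 242 ± 37.1 CPM in APP_PS1, without overlap between the libraries (exact permutation p = 0.1, the smallest possible). Rgs5, a pericyte regulator of G protein signalling, stood at 30.9 ± 15 CPM against 4.98 ± 2.93 without passing the threshold in the quasi-likelihood test (2.63 ± 0.548, FDR 0.596). DESeq2 (adjusted p = 8.84e-05) and the edgeR exact test (adjusted p = 0.00432) called Rgs5, and limma-voom did not. The fibroblast list had 6 of 6 tested members above 0 at low levels, with Col3a1 at 4.39 ± 2.68 CPM against 0.256 ± 0.323 and Dcn at 1.82 ± 1.31 against 0.142 ± 0.21. It was called by camera (adjusted p = 2.17e-05, and adjusted p = 0.0761 with an estimated correlation) and by fry (adjusted p = 0.012).

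**Figure D2:**
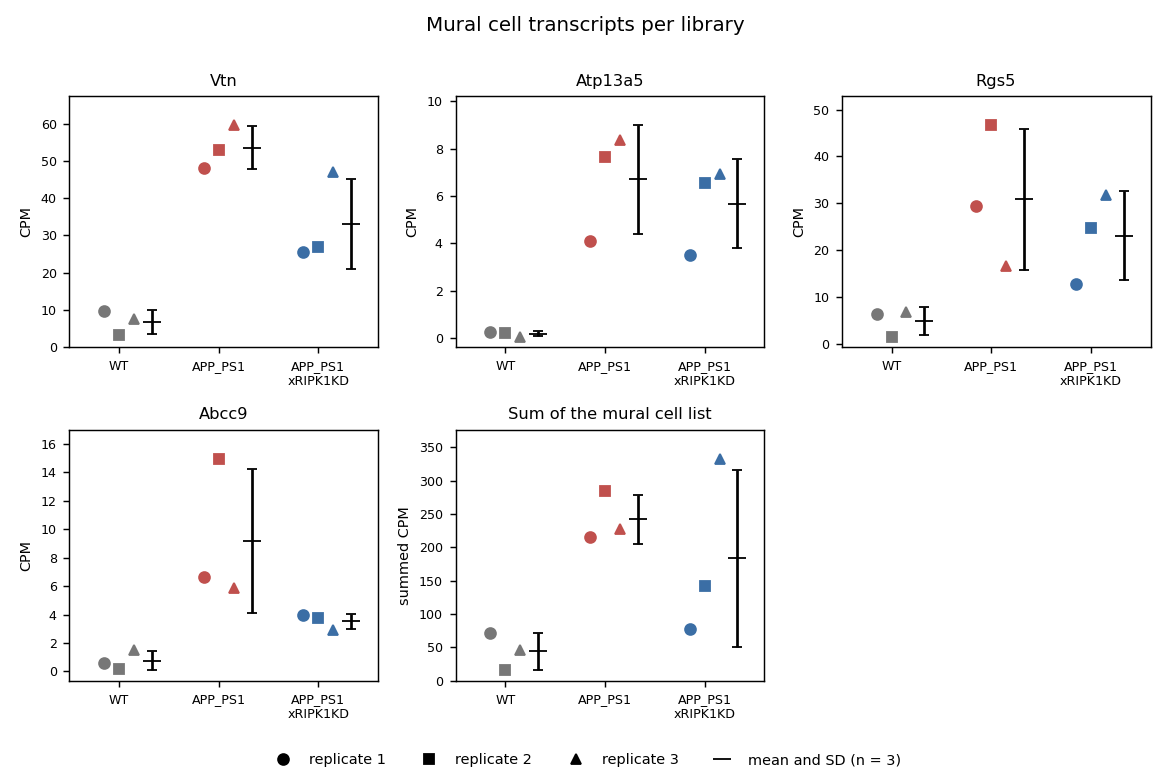
Vtn, Atp13a5, Rgs5 and Abcc9 (CPM) and the sum of the 16 mural cell transcripts (summed CPM) in each library, by genotype, with the symbol giving the replicate and bars giving mean and SD (n = 3). The summed level is 44.6 CPM in WT, 242 CPM in APP_PS1 and 184 CPM in APP_PS1xRIPK1KD, where single libraries range from 77 to 332 CPM.

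Lists of other brain cells were called higher by camera in APP_PS1 as well, while their summed levels overlapped with WT. For oligodendrocytes, the myelin gene Mbp stood at 7.13 ± 5.97 CPM against 0.858 ± 0.676 in WT, and camera called the list (adjusted p = 0.00704, and adjusted p = 0.365 with an estimated correlation). For astrocytes, Gjb6 and Ntsr2 had 0 counts in all 3 WT libraries and 1.14 ± 0.781 and 1.09 ± 0.314 CPM in APP_PS1, at least 14.8-fold and at least 14-fold higher against the mean floor of 3 counts per library. The astrocyte list was called (adjusted p = 0.000503, and adjusted p = 0.365 with an estimated correlation), with a median of 1.37, or 1.48 with members at 0 set to their bound. Microglial transcripts such as Cx3cr1, at 1.48 ± 0.555 CPM against 0.438 ± 0.194, and Fcrls, at 2.35 ± 1.17 against 0.937 ± 1.02, gave adjusted p = 0.0145, and adjusted p = 0.529 with an estimated correlation. Choroid plexus transcripts gave adjusted p = 0.02, and adjusted p = 0.528 with an estimated correlation, with Kcnj13 at 2.65 ± 3.34 CPM against 0.209 ± 0.0255. Without APP_PS1 replicate 3, the calls of oligodendrocytes (adjusted p = 0.113), astrocytes (0.0998) and microglia (0.583) ended. The microglial call also ended without WT replicate 3 (0.192) and the choroid plexus call without APP_PS1 replicate 2 (0.106) and without the filter on low counts (0.0543). Summed levels were 657 ± 61.7 CPM against 665 ± 82 in WT for oligodendrocytes (exact permutation p = 1), 176 ± 30 against 163 ± 44.7 for astrocytes (p = 0.7), 175 ± 56.3 against 157 ± 17.6 for microglia (p = 0.8) and 284 ± 80.7 against 218 ± 21.1 for the choroid plexus (p = 0.4). With replicates 1 and 2 only, a setting chosen after seeing the data, 6 calls of this comparison ended: oligodendrocytes (adjusted p = 0.278), astrocytes (0.178), microglia (0.922, pointing lower), choroid plexus (0.0919), antigen presentation (0.178) and oxidative phosphorylation (0.151). This setting keeps only the libraries with Xist, and the smaller number of libraries can also end calls. At the preset correlation the mural and fibroblast calls stayed in all 14 settings of samples, scaling and filter, with adjusted p up to 1.95e-10 and 0.00157, but they ended with an estimated correlation (0.0858 and 0.0761).

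Among functional lists, immediate early and dissociation response genes were called higher in APP_PS1 (adjusted p = 4.4e-05, and adjusted p = 0.528 with an estimated correlation), with 21 of 25 members above 0 and 3 past the threshold when adjusted over the list alone. The transcription factor Fos stood at 182 ± 97 CPM against 31.9 ± 3.24 (2.51 ± 0.554, FDR 0.707) and Cyr61, a secreted matrix protein, at 154 ± 99.1 against 44.5 ± 12.6 (1.79 ± 0.437, FDR 0.741). DESeq2 called Fos (adjusted p = 0.009), the edgeR exact test called Fos (0.00722) and Cyr61 (0.0482), and limma-voom called neither. Antigen presentation genes were called lower, all 20 below 0 with a median of -0.57 (adjusted p = 0.000151, and adjusted p = 0.558 with an estimated correlation), with H2-M3 at 35 ± 4.49 CPM against 53.9 ± 8.78 and Tap2 at 136 ± 17.6 against 193 ± 57.9. WT replicate 3 stood apart in this list. There the class II invariant chain Cd74, chosen after its values were seen, reached 356 CPM against 6.11 and 6.54 in the other WT libraries, and the call ended without it (adjusted p = 0.572). Cytosolic ribosomal proteins were called lower, 49 of 55 below 0 with a median of -0.14 (adjusted p = 4.4e-05, and adjusted p = 0.558 with an estimated correlation), Rpl27 at 108 ± 6.95 CPM against 133 ± 8.24. So were vascular basement membrane genes (median -0.21, adjusted p = 0.0168, and adjusted p = 0.529 with an estimated correlation), with Lamb1 at 2.36 ± 1.96 against 8.82 ± 5.79 CPM and Hspg2 at 136 ± 32.3 against 218 ± 64.4, and nuclear-encoded oxidative phosphorylation genes (median -0.1, adjusted p = 0.0294, and adjusted p = 0.64 with an estimated correlation). The basement membrane call ended without any 1 of WT replicates 1 (adjusted p = 0.0939) and 2 (0.164) and APP_PS1 replicates 1 (0.0574) and 2 (0.0862). The oxidative phosphorylation call ended without any 1 of WT replicates 1 (0.0939) and 2 (0.116) and APP_PS1 replicates 1 (0.509) and 3 (0.137).

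The lists closest to the endothelial barrier and to Ripk1 were not called in APP_PS1 against WT. Blood-brain barrier junctions and transporters gave adjusted p = 0.44 with 15 of 30 members above 0, pan-endothelial identity 0.112, endothelial Wnt signalling 0.881, the necroptosis and RIPK1 complex list 0.183, NF-kB and TNF targets 0.329 and interferon-stimulated genes 0.178. Arterial endothelium gave 0.176, venous endothelium 0.44, tip cells 0.514, the unfolded protein response 0.28, cholesterol synthesis 0.176, the cell cycle 0.848 and amyloid processing and clearance 0.844. Of the cell types, plaque-associated microglia gave 0.117, leukocytes 0.241, platelets 0.486, erythroid cells 0.112 and neurons 0.482. Ripk1 itself stood at 56.3 ± 17.5 CPM against 42.7 ± 6.89 in WT (FDR 0.834), Casp8 at 68.7 ± 2.04 against 63.6 ± 10.3 (FDR 0.96), Mlkl at 16 ± 1.5 against 12.5 ± 2.31 (FDR 0.907), Ripk3 at 5.22 ± 1.99 against 4.71 ± 1.18 (FDR 0.988) and Tnfaip3 at 23.5 ± 7.81 against 13.7 ± 5.93 (FDR 0.796). Counted at the mouse gene, App stood at 1830 ± 154 CPM against 2090 ± 190 (FDR 0.852). The N-acetyltransferase genes were low: Nat2 stood at 5.56 ± 1.09 CPM against 4.68 ± 0.81 (FDR 0.974), and Nat1 had 0 counts in all 3 APP_PS1 libraries and 0 to 55 counts in WT, at least 6.41-fold lower than the WT mean of 0.65 ± 0.736 CPM (FDR 0.795).

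Several other transcripts of at least 5 CPM differed without overlap of the libraries and without passing the threshold in the quasi-likelihood test. The transmembrane protein Tmem252 stood at 140 ± 24.5 CPM in APP_PS1 against 251 ± 23.1 in WT (FDR 0.156) and Kbtbd11 at 110 ± 7.34 against 182 ± 16.3 (FDR 0.18). Galnt15, Stoml1 and Crtc2 were on the same side, with log2 fold changes of -0.92, -0.88 and -0.72. On the other side were the kinase Braf at 46.1 ± 2.72 against 29 ± 0.542 CPM (FDR 0.707) and the vessel-destabilising ligand Angpt2 at 27.9 ± 3.82 against 13.3 ± 1.43 (FDR 0.707). DESeq2 called Tmem252 (adjusted p = 0.00015), Kbtbd11 (0.000774), Galnt15 (0.00611), Stoml1 (0.0246), Braf (0.0265) and Angpt2 (0.037). The exact test of edgeR called Tmem252 (adjusted p = 0.00432), Kbtbd11 (0.0119) and Galnt15 (0.0301), and limma-voom called none of these genes. The count of 3 called genes became 1 without WT replicate 3, when Vtn and Atp13a5 missed the threshold, and 5 without APP_PS1 replicate 2. It was 2 without APP_PS1 replicate 3, of which 1 was among the 3. Without replicate 3 of each genotype 3 genes were called, of which 1 was among the original 3. Vtn and Atp13a5 missed the threshold in both of these settings.

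The table the authors deposited for the same comparison held 12460 genes, of which 26 passed an FDR of 0.05, 20 higher and 6 lower. Across the 11541 genes found in both tables, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.909 and a Spearman correlation of 0.93. All 26 genes had the same sign here, 25 had an unadjusted p under 0.05 and 3 passed the threshold, Vtn and Atp13a5 among them. In the authors' table Vtn had a log2 fold change of 2.99 (FDR 2.7e-11), Atp13a5 4.87 (FDR 9.11e-10), Fos 2.52 (FDR 0.000186) and Rgs5 2.69 (FDR 0.00062). The likelihood ratio test named in that table, run here on 6 libraries after seeing the data, called 16 of the 26. Of the authors' gene names, 672 were absent from the count matrix.

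The comparison of the compound genotype with APP_PS1 asks how an altered Ripk1 changes the endothelial transcripts of amyloid-bearing mice. It gave 1 called transcript, the long non-coding RNA 2610035D17Rik, encoded on the minus strand of chromosome 11 from 113043895 to 113201838. It had 0 counts in all 3 libraries of the compound genotype and 8.11 ± 3.37 CPM in APP_PS1, with 170 to 470 counts per library (FDR 0.0137). Against the mean floor of 3 counts per library, it was at least 133-fold lower. Transcripts of mural cells and fibroblasts, of oligodendrocytes and of the immediate early and dissociation response were called lower as lists by camera. With an estimated correlation these lists gave adjusted p = 0.752, 0.352, 0.352 and 0.606. No transcript was called higher. At an unadjusted p under 0.05 edgeR counted 325 genes higher and 312 lower, 637 in all against 666 expected by chance, and DESeq2 called 10 higher and 9 lower.

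Immediate early and dissociation response genes had 22 of 25 members below 0, with a median of -0.46 (camera adjusted p = 4.69e-06, and adjusted p = 0.606 with an estimated correlation). The higher call of this list in APP_PS1 against WT used the same APP_PS1 libraries. Between the compound genotype and WT the list was not called (median -0.016, camera adjusted p = 0.857). Egr1 stood at 19 ± 7.47 CPM against 39.7 ± 15 in APP_PS1 and Junb at 57.8 ± 13.9 against 124 ± 58.9. Venous endothelial genes had 12 of 14 below 0 with a median of -0.92 (adjusted p = 0.000611, and adjusted p = 0.687 with an estimated correlation). The interleukin 1 receptor Il1r1 stood at 42.9 ± 9.49 CPM against 94.4 ± 31.1 and the oxysterol-forming enzyme Ch25h at 9.01 ± 1.28 against 26.2 ± 5.97. Antigen presentation genes had 17 of 20 below 0 (median -0.34, adjusted p = 0.0292, and adjusted p = 0.758 with an estimated correlation). There the class I transactivator Nlrc5 stood at 17.5 ± 3.62 against 39 ± 11.9 CPM and B2m at 1980 ± 333 against 2680 ± 446. Cytosolic ribosomal proteins gave a median of -0.08 (adjusted p = 0.0479, and adjusted p = 0.758 with an estimated correlation), with Rplp1 at 138 ± 16.9 CPM against 195 ± 34.4. Tip cell genes were called higher, 12 of 18 above 0 with a median of 0.37 (adjusted p = 0.0184, and adjusted p = 0.687 with an estimated correlation). Esm1, a proteoglycan of sprouting endothelium, stood at 69.9 ± 25.3 CPM against 30.6 ± 12.6 and the basement membrane protein Nid2 at 57.5 ± 21.3 against 32.2 ± 5.13. No member of these lists passed the threshold over all genes in the quasi-likelihood test. The likelihood ratio test on 6 libraries, chosen after seeing the data, called Il1r1 (FDR 0.0146), Ch25h (0.000596) and Nlrc5 (0.0372), and no other setting called them. The antigen presentation call ended without any 1 of APP_PS1 replicate 3 (adjusted p = 0.432) and replicates 2 (0.109) and 3 (0.19) of the compound genotype, and the tip cell call without any 1 of APP_PS1 replicates 1 (0.0524) and 2 (0.0882) and replicates 1 (0.094) and 2 (0.22) of the compound genotype. At the preset correlation the ribosomal call ended in 9 of 14 settings, with adjusted p up to 0.977 with replicates 1 and 2 only, and pointed higher without APP_PS1 replicate 3 (0.799). With replicates 1 and 2 only the antigen presentation call ended too (0.465).

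Mural cell transcripts had 15 of 16 members below 0 with a median of -0.43 (adjusted p = 0.00354, and adjusted p = 0.752 with an estimated correlation). Vtn stood at 33.1 ± 12.1 CPM against 53.5 ± 5.69 (FDR 1) and Abcc9, the sulfonylurea receptor of pericytes, at 3.51 ± 0.556 against 9.16 ± 5.05. Summed over the list the compound genotype stood at 184 ± 132 CPM, which overlapped the 242 ± 37.1 CPM of APP_PS1 (exact permutation p = 0.4), and the call ended without replicate 1 of the compound genotype (adjusted p = 0.178). Fibroblast transcripts had 6 of 6 below 0 (adjusted p = 0.00354, and adjusted p = 0.352 with an estimated correlation) and a summed level of 6.31 ± 1.94 against 13.2 ± 2.41 CPM. Their call ended without APP_PS1 replicate 3 (adjusted p = 0.054) and without the filter on low counts (0.0671). Oligodendrocyte transcripts had 8 of 9 below 0 (adjusted p = 0.00303, and adjusted p = 0.352 with an estimated correlation). Most of their summed level came from Mal, which stood at 428 ± 62.2 CPM against 599 ± 54 and was lower when adjusted over the list alone, and the call ended without APP_PS1 replicate 3 (adjusted p = 0.101). Choroid plexus transcripts were called higher, 6 of 6 above 0 (adjusted p = 0.0475, and adjusted p = 0.687 with an estimated correlation), with the thyroid hormone carrier Ttr at 222 ± 67.9 against 104 ± 47 CPM and Enpp2 at 199 ± 15.6 against 172 ± 40.3. At the preset correlation that call ended in 9 of 14 settings, with adjusted p up to 0.465. With replicates 1 and 2 only, the fibroblast (0.0515) and oligodendrocyte (0.246) calls ended too. Of the 20 lists not called, the vascular basement membrane gave the smallest adjusted p, 0.0942.

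Ripk1 transcripts stood at 37.3 ± 6.91 CPM in the compound genotype, 56.3 ± 17.5 in APP_PS1 and 42.7 ± 6.89 in WT, so the gene was transcribed in all 3 genotypes. The log2 fold change against APP_PS1 was -0.59 ± 0.23 (FDR 0.98) and against WT -0.2 ± 0.229 (FDR 0.986). The necroptosis and RIPK1 complex list gave adjusted p = 0.492 against APP_PS1 with 15 of 26 members above 0, and NF-kB and TNF targets gave 0.14. Casp8, Mlkl, Ripk3 and Tnfaip3 stood at 73.2 ± 6.89, 13.2 ± 4.57, 5.42 ± 2.31 and 22.8 ± 5.17 CPM in the compound genotype, none of them past the threshold. Among genes of at least 5 CPM without overlap of the libraries, the glucocorticoid-induced chaperone Fkbp5 had the smallest p after 2610035D17Rik, at 6.27 ± 1.95 CPM against 23 ± 11.2 (-1.88 ± 0.352, FDR 0.696). The DNA sensor Aim2 stood at 4.22 ± 0.299 against 11.5 ± 0.796 CPM and the folate enzyme Mthfd1l at 4.4 ± 0.903 against 15.3 ± 6.41. Higher in the compound genotype without passing the threshold in the quasi-likelihood test were Plscr2 at 174 ± 16.6 against 75.5 ± 35.2 CPM, Alox12 at 74.7 ± 7.29 against 38.2 ± 4.42 and Lhfpl2 at 91.5 ± 13.6 against 50.8 ± 8.34. DESeq2 and the edgeR exact test each called Fkbp5, Aim2, Mthfd1l, Plscr2, Alox12 and Lhfpl2. Their adjusted p ran from 0.00121 (Fkbp5, DESeq2) to 0.0318 (exact test). Leaving out any 1 of APP_PS1 replicates 1 and 3 and replicates 1 and 3 of the compound genotype gave 0 called genes, and leaving out replicate 2 of either gave 4. limma-voom called 0.

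**Figure D3:**
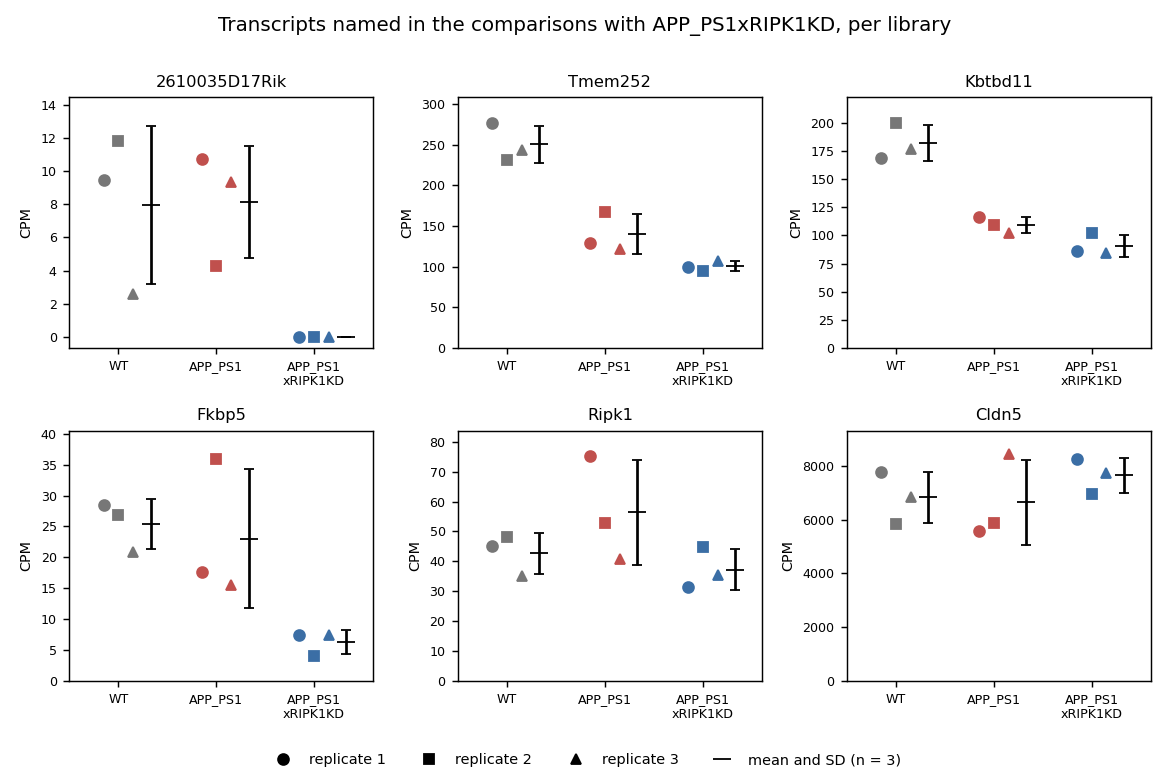
2610035D17Rik, Tmem252, Kbtbd11, Fkbp5, Ripk1 and Cldn5 (CPM) in each library, by genotype, with the symbol giving the replicate and bars giving mean and SD (n = 3). 2610035D17Rik is at 0 in all 3 libraries of APP_PS1xRIPK1KD and at 8.11 CPM on average in APP_PS1, while Ripk1 means are 42.7, 56.3 and 37.3 CPM from left to right.

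Compared with WT, the compound genotype carried more of 2 transcripts, among them Atp13a5, and less of 3. Atp13a5 stood at 5.67 ± 1.88 against 0.18 ± 0.104 (4.98 ± 0.645, FDR 0.0122). Tmem252, on chromosome 19 from 24674008 to 24682233, was 2.5-fold lower at 100 ± 6.12 CPM against 251 ± 23.1 (-1.32 ± 0.145, FDR 0.00696). Kbtbd11, a Kelch and BTB domain protein on chromosome 8 from 15011025 to 15033333, was 2.01-fold lower at 90.8 ± 9.92 CPM against 182 ± 16.3 (-1.01 ± 0.13, FDR 0.0122). 2610035D17Rik was again at 0 counts against 7.95 ± 4.78 CPM in WT, at least 130-fold lower (FDR 0.00696). At an unadjusted p under 0.05 edgeR counted 396 genes higher and 427 lower, 823 in all against 666 expected by chance, and DESeq2 called 29 higher and 33 lower.

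Mural cell transcripts had 15 of 16 members above WT, with a median of 2.2, and 10 were higher when adjusted over the list alone (camera adjusted p = 1.67e-13, and adjusted p = 0.317 with an estimated correlation). Vtn, at 33.1 ± 12.1 CPM against 6.79 ± 3.26, missed the threshold in the quasi-likelihood test (2.29 ± 0.355, FDR 0.0501). It passed with unrounded counts (FDR 0.0499) and upper-quartile factors (0.0488), with DESeq2 (5.46e-08) and with the edgeR exact test (2.08e-06). It did not pass with limma-voom, RLE factors or the replicate block. Choroid plexus transcripts had 6 of 6 above 0, with 3 higher when adjusted over the list alone (adjusted p = 4.66e-05, and adjusted p = 0.317 with an estimated correlation). Ttr stood at 222 ± 67.9 CPM against 54.4 ± 14.5 (2.03 ± 0.374, FDR 0.251) and Kcnj13 at 2.74 ± 0.753 against 0.209 ± 0.0255. DESeq2 (adjusted p = 1.04e-07) and the edgeR exact test (adjusted p = 0.00015) called Ttr, and limma-voom did not. Astrocyte transcripts gave a median of 1.14 (adjusted p = 0.000331, and adjusted p = 0.43 with an estimated correlation), with Gjb6 and Ntsr2 at 0.299 ± 0.289 and 0.243 ± 0.221 CPM against 0 counts in WT, at least 3.87-fold and at least 3.15-fold higher by group means. Counts in the compound genotype ran from 0 to 32 for Gjb6 and from 0 to 24 for Ntsr2, so the bounds do not hold for every library. The astrocyte call ended without replicate 3 of the compound genotype (adjusted p = 0.0534) and with replicates 1 and 2 only (0.255). Summed levels were 161 ± 11.8 CPM against 163 ± 44.7 in WT for astrocytes (exact permutation p = 0.9) and 432 ± 72.6 against 218 ± 21.1 for the choroid plexus (p = 0.1, the smallest possible). Fibroblast transcripts were not called (adjusted p = 0.19), although their summed level of 6.31 ± 1.94 CPM did not overlap the 1.47 ± 0.906 CPM of WT (exact permutation p = 0.1, the smallest possible).

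Antigen presentation genes stood below WT in all 20 members with a median of -1.04, and 12 were lower when adjusted over the list alone (adjusted p = 8.9e-10, and adjusted p = 0.631 with an estimated correlation). The class I heavy chain H2-D1 stood at 1990 ± 200 CPM against 3120 ± 927 and Nlrc5 at 17.5 ± 3.62 against 57.5 ± 45. Without WT replicate 3, the library with high Cd74, the adjusted p of the antigen presentation list was 0.000226. Interferon-stimulated genes had 25 of 33 below 0 with a median of -0.33 (adjusted p = 0.00945, and adjusted p = 0.854 with an estimated correlation), with Ifitm3 at 598 ± 25.1 against 807 ± 167 CPM and Mx2 at 15.2 ± 2.03 against 23.6 ± 5.9. Venous endothelial genes had 12 of 14 below 0 with a median of -0.72 (adjusted p = 0.00979, and adjusted p = 0.707 with an estimated correlation), with Il1r1 at 42.9 ± 9.49 CPM against 115 ± 50.8 and Ch25h at 9.01 ± 1.28 against 29.1 ± 28.5. Without WT replicate 3 the interferon (adjusted p = 0.694, pointing higher) and venous (0.571) calls ended, and both ended with replicates 1 and 2 only (0.487 each, the interferon list pointing higher). The interferon call also ended without replicate 3 of the compound genotype (0.197) and the venous call without its replicate 1 (0.0846). Cytosolic ribosomal proteins had all 55 members below 0 with a median of -0.21 (adjusted p = 1.54e-10, and adjusted p = 0.631 with an estimated correlation), Rplp1 at 138 ± 16.9 CPM against 241 ± 40 and Rps24 at 146 ± 4.48 against 186 ± 6.32. DESeq2 called Il1r1 (adjusted p = 0.00234), Rplp1 (0.00394) and Nlrc5 (0.0105). The edgeR exact test called Il1r1 (adjusted p = 0.0206) and Rplp1 (0.0295), and limma-voom called none of these genes. Summed as a share of all counts, a measure chosen after seeing the data, the 55 transcripts were not lower, at 1.15% ± 0.0842 in the compound genotype, 1.17% ± 0.0995 in APP_PS1 and 1.12% ± 0.0553 in WT (exact permutation p = 0.6 for each against WT). As a share of the counts without Rn45s they stood at 1.49% ± 0.0513, 1.54% ± 0.127 and 1.66% ± 0.0747, with exact permutation p = 0.1, the smallest possible, for the compound genotype and 0.3 for APP_PS1 against WT. At the TMM scale their summed level was 10800 ± 387 CPM in the compound genotype and 12300 ± 619 in WT (exact permutation p = 0.1). At the preset correlation the camera call against WT stayed in all 14 settings, removal of Rn45s among them, with adjusted p up to 7.92e-06. The treatment of Rn45s thus changed the share of all counts but not the list call. Removing Rn45s shifted the log2 fold changes at the TMM scale by a median of only 0.0018. The kept call therefore does not test whether the ribosomal difference is tied to Rn45s. The mean Rn45s share was 23% ± 3.15 in the compound genotype and 32.3% ± 2.32 in WT. Of the 22 lists not called, tip cells and microglia gave the smallest adjusted p, 0.067 each.

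Other transcripts differed from WT without overlap of the libraries and without passing the threshold in the quasi-likelihood test. Fkbp5 stood at 6.27 ± 1.95 CPM against 25.4 ± 4.02 (-2.02 ± 0.353, FDR 0.117) and the choline kinase Chka at 39.5 ± 7.81 against 96.5 ± 25.7 (FDR 0.0932). Higher were Dpysl2 at 283 ± 11 CPM against 192 ± 8.86 (FDR 0.251) and the kinase Plk2 at 311 ± 30.8 against 210 ± 10.6 (FDR 0.27). DESeq2 called Fkbp5 (adjusted p = 3e-05), Chka (3.41e-05), Dpysl2 (0.000638) and Plk2 (0.00364). The edgeR exact test called Fkbp5 (adjusted p = 0.00014) and Chka (0.000136), and limma-voom called none of these genes. App stood at 1970 ± 138 CPM (FDR 0.995), Nat1 at 0.271 ± 0.315 (FDR 0.995) and Nat2 at 6.02 ± 2.51 (FDR 0.982). The count of 5 called genes became 2 without WT replicate 1, without WT replicate 2 or without replicate 1 of the compound genotype, 3 without its replicate 3 and 9 without its replicate 2. limma-voom called 2 genes, and a fit to replicates 1 and 2 of each genotype, chosen after seeing the data, called 8, of which 3 were among the 5.

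No gene was called with opposite signs in APP_PS1 against WT and in the compound genotype against APP_PS1. At an unadjusted p under 0.05 in both, edgeR gave 128 genes with opposite and 5 with the same sign, but both comparisons use the 3 APP_PS1 libraries, with opposite signs, so that such pairs arise without any effect. Across all genes the log2 fold changes had a correlation of -0.513, and simulated counts without group effects gave -0.507 on average, from -0.533 to -0.48 over 100 draws. The covariance was -0.262, below all simulated values, which averaged -0.209 and ran from -0.227 to -0.194. The genes were simulated independently of each other, which can make these ranges too narrow. With the correlation inside its simulated range, the covariance does not show a reversal. DESeq2 called 1 gene with opposite signs, the mitotic motor Kif4, which had 0 counts in all 3 APP_PS1 libraries and 16 to 115 in WT, at least 15.4-fold lower in APP_PS1 (edgeR FDR 0.707). Of the genes called higher in APP_PS1, the log2 fold change of the compound genotype against APP_PS1 was -0.69 ± 0.337 for Vtn and -0.25 ± 0.524 for Atp13a5, each with an FDR of 1.

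Of the 33 comparisons of summed cell type levels, 12 had no overlap between the 3 libraries of each genotype, against a share of 10% by chance, and no exact permutation p was under 0.1. The 33 comparisons reuse the same 9 libraries and are not independent, so the 12 cannot be tested against that share. For some lists, none of them called in the comparison concerned, the median, the mean and the direction of camera differed in sign. In APP_PS1 against WT these were venous endothelium (median -0.04, mean -0.29, camera higher), NF-kB and TNF targets, the cell cycle, amyloid processing and platelets. In the compound genotype against APP_PS1 they were neurons and astrocytes. Against WT they were blood-brain barrier genes, the unfolded protein response, the cell cycle and oligodendrocytes (median 0.19, mean 0.94, camera lower with adjusted p = 0.959).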

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

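The number of called genes depended on the test more than on scaling. APP_PS1 against WT gave 3 genes, and 45 with DESeq2, 14 with the edgeR exact test, 7 without the filter on low counts, 5 at an FDR of 0.1, 29 with the likelihood ratio test on 9 libraries and 50 on 6, 1 without WT replicate 3 and 5 without APP_PS1 replicate 2. The compound genotype against APP_PS1 gave 1 gene, and 19 with DESeq2, 11 with the exact test, 0 with limma-voom, the replicate block or replicates 1 and 2 only, 17 and 35 with the likelihood ratio test on 9 and 6 libraries, 0 without APP_PS1 replicate 1 and 4 without APP_PS1 replicate 2. The compound genotype against WT gave 5 genes, and 62 with DESeq2, 32 with the exact test, 2 with limma-voom, 8 with upper-quartile factors, unrounded counts or replicates 1 and 2 only, 14 without the filter, 9 with the stricter filter or an FDR of 0.1, 3 with only the 6 libraries compared, 0 with the replicate block, 47 and 74 with the likelihood ratio test on 9 and 6 libraries, 2 without WT replicate 1 and 9 without replicate 2 of the compound genotype. The likelihood ratio tests, replicates 1 and 2 only, replicate 3 as a term and removal of Rn45s were chosen after seeing the data. With replicate 3 as a term, or with Rn45s removed, the counts stayed at 3, 1 and 5.

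Camera called 11 lists in APP_PS1 against WT, with 0 at an estimated correlation, 2 with fry, 7 without APP_PS1 replicate 3 and 13 without WT replicate 3. It called 9 in the compound genotype against APP_PS1, with 0 at an estimated correlation, 0 with fry, 5 with replicates 1 and 2 only or without APP_PS1 replicate 3 and 11 without APP_PS1 replicate 2. It called 7 in the compound genotype against WT, with 0 at an estimated correlation, 0 with fry, 6 without WT replicate 3 and 11 without WT replicate 2. The direction of 4 list results turned, without a call: microglia in APP_PS1 against WT with replicates 1 and 2 only (adjusted p = 0.922), ribosomal proteins in the compound genotype against APP_PS1 without APP_PS1 replicate 3 (0.799, and 0.00149 at the lowest, without APP_PS1 replicate 1), and interferon-stimulated genes in the compound genotype against WT without WT replicate 3 (0.694, and 5.51e-07 at the lowest, without WT replicate 1) and with replicates 1 and 2 only (0.487). No called gene changed sign in the 25 settings. Of the named genes that were not called, signs changed in 19 cases with a library left out and in 2 with another setting. Summed cell type levels changed sign in 24 cases with a library left out and, with another scaling or the median of members, in 4 within and 9 beyond the spread between replicates. Opposite changes numbered 0, and 1 with DESeq2. Of the 26 genes past the authors' own threshold, 3 were called here, and 16 with the exact test on 6 libraries, 14 and 16 with the likelihood ratio test on 9 and 6 libraries. Of 25 settings, Vtn in APP_PS1 against WT was called in 21 and Atp13a5 in 18. 2610035D17Rik was called in 18 against APP_PS1 and in 22 against WT, Tmem252 in 23 and Kbtbd11 in 18. The replicate numbers are not given as pairs in the labels, and 4 of 9 libraries correlated best with a library of their own number, the 3 of replicate 3 (0.0391 to 0.0983 among themselves) and WT replicate 1. The cause of these dependences was not tested.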

Other observations

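Further transcripts varied between the libraries in sets known to move together. The lists and the relation in this paragraph and the next were chosen only after the values were seen. Heat shock factor targets, tested without Hsp90aa1, Hsph1 and Hspa4l, which prompted the list, had 16 of 17 members above 0 in APP_PS1 against WT with a median of 0.49 (camera adjusted p = 6.24e-06, and adjusted p = 0.246 with an estimated correlation). Its members Hspa1a, Hspa1b and Dnajb1 belong also to the immediate early and dissociation response list. Glucocorticoid receptor targets, tested without Fkbp5, which prompted the list, had 12 of 15 below 0 in the compound genotype against WT with a median of -0.58 (adjusted p = 0.000405, and adjusted p = 0.285 with an estimated correlation). With the estimated correlation, neither a heat shock response nor lower glucocorticoid receptor target expression can be told apart from no difference.

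Clock genes ranged widely across the 9 libraries, with Dbp between 11.2 and 220 CPM and Arntl between 10.4 and 83.3 CPM. Across the 9 libraries the mean of 8 genes of the Dbp phase and the mean of 4 genes of the Arntl phase had a Pearson r of -0.839 (exact 2-sided permutation p = 0.00222, Spearman -0.933 with exact p = 0.00075). It was -0.886 (exact p = 0.00694) without the 2 libraries farthest from the median and -0.95 (exact p = 0.00972) within the 6 libraries with Xist. This is consistent with libraries taken at different times of day, and the times are not given in the sources used here. Per1 belongs both to the Dbp phase and to the glucocorticoid receptor list.

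The test for the mural transcripts in APP_PS1 against WT was chosen only after the result was seen. The shallowest library, APP_PS1 replicate 1, is argued against as the cause by a median log2 fold change of 2.56 without it, beside 2.62 with it. Open are more mural cells in the sorted samples, fewer endothelial cells, and higher levels per cell, which bulk libraries do not separate. The medians of the other cell type lists ran from -0.01 for platelets and 0.18 for neurons to 2.38 for oligodendrocytes and 3.34 for fibroblasts, many of their members having few counts.

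The male label is argued against for the cells of the 6 libraries with Xist. There Xist stood between 264 and 534 CPM, and the summed Y-linked transcripts did not exceed 0.434 CPM. In the other libraries the Y-linked sum lay between 150 and 184 CPM and Xist did not exceed 4.78 CPM, which goes with the label. The sex was not tested apart from these levels, which raised the question.

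The tests for 2610035D17Rik were chosen only after the result was seen, and the windows were set after the region had been looked at. Too few reads are argued against, since 114 counts were due in the shallowest library of the compound genotype at the lowest level of the other 6. A deletion of both copies that takes in the neighbouring genes is argued against by the lowest count of 19 in the nearest tested gene on 1 side, Sox9, and of 106 in Slc39a11 on the other. Both neighbours were lower in the compound genotype without passing the threshold in edgeR, Sox9 with log2 fold changes of -2.86 against APP_PS1 (FDR 0.98) and -2.02 against WT (FDR 0.662) and Slc39a11 with -0.8 (FDR 1) and -1.07 (FDR 0.764), so an effect that reaches them stays open. A stretch of chromosome 11 that differs in the compound genotype cannot be told apart from chance, with a largest Fisher exact p of 0.251 over windows of 2, 5 and 10 Mb, although the 5 Mb window alone gave 0.0496.

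The split counts were planned. Of the 10 ways to split 6 libraries into 3 and 3, too few for a share under 0.05, 1 gave at least as many called genes as the real 3 in APP_PS1 against WT, the real split itself, and the highest other was 0. In the compound genotype against APP_PS1 it was 1, with the real 1 and a highest other of 0. Against WT it was 2, with the real 5 and a highest other of 9, from WT replicates 1 and 3 and replicate 3 of the compound genotype against the rest. For gene lists the splits were 2 (real 11, highest other 11), 2 (real 9, highest other 9) and 4 (real 7, highest other 10) in the same order.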
